A study of Escherichia coli K-12 with 4 samples.

How the data were processed

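The series holds 4 RNA-seq libraries of Escherichia coli K-12 MG1655, 1 from each of 4 groups: wild type with the empty vector pBRplac, wild type with pBRplac-OxyS, hfq mutant with the empty vector and hfq mutant with pBRplac-OxyS. Per the labels' protocols, cells grew in LB with ampicillin, received 0.1 mM IPTG at an OD600 of 0.2 and were harvested at an OD600 of 1.0, RNA was stabilised with a bacterial RNA protection reagent, and libraries were made with an Illumina TruSeq RNA kit, which does not mark strand. Groups were taken from the sample titles, which give plasmid and genotype.

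The authors deposited 2 workbooks, 1 for wild type and 1 for the hfq mutant. Per the file headers, 1 sheet of each held the raw read count per annotated gene, and another held RPKM, reads scaled to gene length and to the library's counted reads, which the authors computed for each library separately. Further sheets with the authors' own scaling of the same counts were not used here. The aligner, the counting tool and their settings are not given in the sources used here. The deposited tables have 4321 rows with MG1655 coordinates. Of these 180 carry no protein identifier. Nearly all lengths are multiples of 3, so they are called coding lengths here. Gene identifiers matched the RefSeq gene table for 4314 rows, and 279 rows carry another symbol there; gene names below are those of the deposited tables. No ribosomal RNA, transfer RNA or small RNA was analysed here, so that the level of OxyS itself is not given. Another 55 rows share 9 insertion sequence names, and near-identical copies such as tufA and tufB may share reads; overlapping and antisense genes cannot be told apart without strand.

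One cell of the deposited counts was treated as missing. The flagellin gene fliC was listed at 0 in the hfq mutant with empty vector, whereas the authors' RPKM values of that library imply 1001592 more reads than its listed counts sum to, or 5.56% of the implied total. In the other 3 libraries this gap was 1399 to 1921 reads. All comparisons that use that cell leave out fliC.

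Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 over all 4 libraries, and expressed as CPM, counts relative to the scaled library size. The factors were 0.976 and 0.979 for wild type with vector and with OxyS, and 0.934 and 1.12 for the hfq mutant with vector and with OxyS. A log2 ratio of 2 libraries used a prior count of 2 scaled to library size. With 1 library per group there is no replicate check and no p-value for the comparisons, so genes were counted by a rule of size: mean CPM of at least 10, a log2 ratio of at least 1 in size, and a 95% exact conditional binomial interval of the ratio that excludes no change. Genes that passed are called higher or lower. Intervals cover counting error only, and reads without molecular identifiers are not independent molecules. Depth was 14793216 to 20362733 counts per library, and 3 counts correspond to 0.147 to 0.203 CPM. The dependence of the OxyS change on Hfq was the log2 ratio in wild type minus that in the hfq mutant, counted by the same rule over all 4 libraries with a normal interval.

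A total of 30 gene lists were fixed before the data were examined, and each was described by the median log2 ratio of its compared members and the percentile of that median among 10000 random lists of the same size matched on abundance. A further 8 lists were put together after the values were seen and are named as such. Their percentiles describe values already seen and are no support for a change. The named genes were hfq, the 12 highest and 12 lowest called genes of each of the 3 comparisons, the 6 highest and 6 lowest differences for Hfq dependence, up to 4 members of each list with the largest log2 ratio in size, and every member of the lists of earlier OxyS targets, the lac operon and the hfq operon with its neighbours. Genes named outside this rule are said to be chosen after their values were seen.

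The rule of size was tested on simulated counts. It recovered 97 of 97 genes given a log2 change of 1.5 and 93 of 93 given 2.5 for OxyS in wild type, among 2723 genes, and called 0 of 2533 unchanged genes; the other comparisons had recovery of 100% at both sizes. These simulations carry counting error alone and changes well past the size needed, so they check the computation and say nothing of variation between cultures, which 1 library per group cannot show. An additive model was added after seeing the data: edgeR's quasi-likelihood test with terms for genotype and plasmid over the 4 libraries, with 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. It assumes that both effects add on the log scale. On simulated counts it recovered 95 of 96 genotype changes and 47 of 47 plasmid changes of log2 size 1.5 among 2717 genes, with 0 unchanged genes called, again with counting error alone. The plasmid changes counted were alike in both backgrounds, so recovery of changes present in only 1 background was not checked.

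Alternatives fixed beforehand were RLE factors, total counts, upper-quartile factors, total counts without the 20 most abundant genes, no filter on low counts, mean CPM of at least 50, prior counts of 0.5 and 10, the authors' RPKM as log2(RPKM + 1), and a log2 ratio of at least 2 in size. Added after seeing the data were TMM without fliC, the fliC cell taken as 0, the hfq comparison in the OxyS pair of libraries, the additive model, and ratios centred on the median of each of 10 groups of genes by coding length or by abundance. Statistics used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.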

Results

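The transcriptome of Escherichia coli K-12 MG1655 was compared with and without overexpression of OxyS, in wild type and in an hfq mutant. OxyS is a small regulatory RNA made under oxidative stress, and Hfq is the RNA chaperone through which OxyS and many other small RNAs reach their target mRNAs. OxyS was expressed from the IPTG-inducible plasmid pBRplac, and the empty plasmid served as control. Each of the 4 groups had 1 library, so no value below has a replicate error. The libraries held 20362733 counts in wild type with vector, 16265976 in wild type with OxyS, 17012324 in the hfq mutant with vector and 14793216 in the hfq mutant with OxyS. The 10 most abundant genes took 18.9% to 19.9% of the counts in the 3 libraries other than the hfq mutant with vector, where the abundant gene fliC was listed at 0 and treated as missing.

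Transcripts of hfq were present in wild type and nearly absent from both libraries labelled hfq mutant. The gene (b4172, positions 4400288 to 4400596, plus strand) had 4853 counts in wild type with vector, 244 CPM with a counting interval of 237.3 to 251, and 3303 counts in wild type with OxyS, 207 CPM (200.4 to 215). In the mutant it had 1 count with vector, 0.0630 CPM (0.00159 to 0.351), and 2 counts with OxyS, 0.121 CPM (0.0146 to 0.436). The wild type to mutant ratio was 3877 with vector (696 to 153200) and 1719 with OxyS (476 to 14200). Of the genes around hfq, miaA, which lies upstream of it and encodes a tRNA modification enzyme, was higher in the mutant with vector, with a log2 ratio of 1.26 (1.22 to 1.29). Its downstream neighbours hflX, hflK and hflC were at -0.51, -0.71 and -0.76 and were not called. Values of the more distant purA, mutL and nsrR were -0.28, -0.10 and 0.15. Between mutant and wild type with OxyS, miaA was at 2.96, and hflX, hflK and hflC were at 0.11, -0.23 and -0.16.

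The first comparison asked which mRNAs differ with OxyS when Hfq is present. In wild type, 38 of 2696 compared genes were higher with OxyS and 5 were lower. Most of the largest increases lay in sulfate uptake and cysteine synthesis. Of 17 compared genes of this pathway, controlled by the activator CysB, 16 were higher and none was lower, with a median log2 ratio of 1.94, or 3.85-fold, at percentile 100 of random lists; the list was put together after the values were seen. The sulfate and thiosulfate transporter genes cysU, cysP, cysW and cysA reached 2.53 (2.37 to 2.72), 2.51 (2.41 to 2.62), 2.35 (2.22 to 2.49) and 2.19 (2.10 to 2.28). The sulfite reductase genes cysJ and cysI reached 2.37 (2.31 to 2.44) and 1.94, the ATP sulfurylase genes cysD and cysN 2.32 and 2.06, and the adenylylsulfate kinase gene cysC 2.08. For cysJ the level was 110 CPM with vector and 570.3 CPM with OxyS. Outside the pathway, ycfJ went from 3.57 to 17.8 CPM (log2 ratio 2.28, 1.94 to 2.71), ypfG from 4.22 to 20.8 CPM (2.27, 1.95 to 2.66) and puuC, a dehydrogenase of putrescine breakdown, from 5.13 to 22.7 CPM (2.12, 1.83 to 2.48).

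The 5 lower genes included both asparagine synthetase genes, asnA at -1.47 (-1.52 to -1.41) and asnB at -1.07 (-1.15 to -0.99). The others were hcaR at -1.29 (-1.44 to -1.16) and mhpR at -1.12 (-1.29 to -0.96), regulators of the breakdown of phenylpropionate compounds, and rsd, which encodes an anti-sigma factor, at -1.03 (-1.19 to -0.88).

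None of the 8 compared genes of the list of earlier OxyS targets was called in wild type, although 7 had ratios below 0 and the median, -0.24, stood at percentile 0.77 of random lists. The cold-shock-like gene cspC and its partner yobF were both at -0.77 (-0.82 to -0.72 and -0.93 to -0.61). The stationary phase sigma factor gene rpoS was at -0.25 (-0.29 to -0.21), the flagellar regulators flhD and flhC were at -0.25 and -0.22, and ybaY was at -0.21. The formate regulator gene fhlA was at 0.30 (0.03 to 0.57) on 11.8 and 14.5 CPM, and nusG was at 522 CPM in both libraries. These counts measure mRNA, so a change in translation alone would not show in them.

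Several lists shifted in wild type by less than the size needed for a call. Heat shock genes of the sigma factor RpoH had a median of 0.33, at percentile 100, with 15 of 21 above 0 and none called; ibpB, a small heat shock protein gene, was at 0.92, and the chaperone genes htpG, groL and groS were at 0.67, 0.63 and 0.62. The list of genes repressed by the small RNA GcvB holds mostly amino acid and peptide transport genes and some of amino acid synthesis. Its median was -0.34, at percentile 0, with 18 of 24 below 0. The genes argT, dppA, cycA and sstT were at -0.90, -0.87, -0.75 and -0.68. Lists that the small RNA Spot 42 represses (median -0.23, percentile 0.22), of cell division (-0.16, percentile 0.78) and of outer membrane porins and channels (-0.13, percentile 1.11) lay below random lists with no gene called. Lists of curli, cellulose and fimbriae (0.31, percentile 99.8) and of arginine and pyrimidine biosynthesis (0.15, percentile 99.6) lay above them with no gene called; the arginine genes argA and argF were at 0.89 and 0.79. Among 30 compared iron uptake genes entC alone was called, at 1.14 (0.96 to 1.34), and the list median was -0.01.

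For 30 of the 43 genes called in wild type, the library farthest from the median of the 4 was wild type with vector, against 12 for wild type with OxyS. The sulfate and cysteine genes had median log2 ratios against wild type with vector of 1.94 in wild type with OxyS, 2.79 in the hfq mutant with vector and 1.87 in the hfq mutant with OxyS. Across genes the ratio in wild type also rose with coding length, with a Spearman rho of 0.27 over 2696 genes. Random lists were matched on abundance and not on coding length, so the percentiles of small list shifts in wild type may carry this trend.

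**Figure D1:**
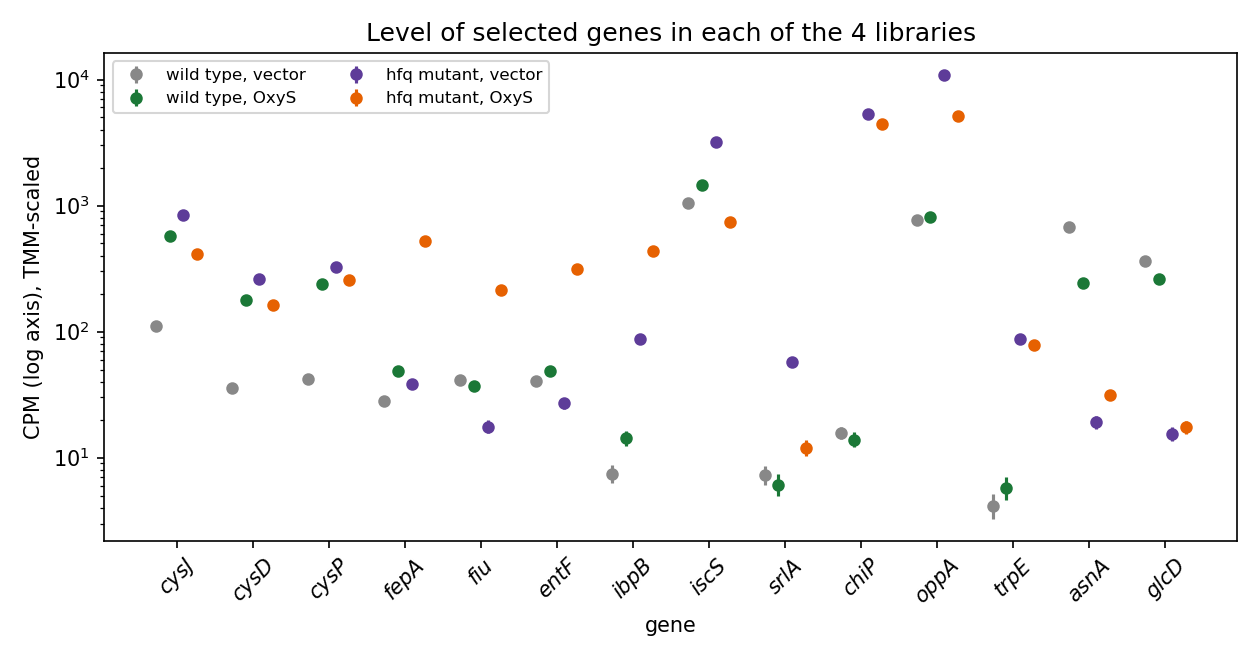
CPM on a log axis of 14 genes in each of the 4 libraries, with bars for the 95% Poisson counting interval. The sulfate and cysteine genes cysJ, cysD and cysP were lowest in wild type with vector, the iron uptake genes fepA, fiu and entF were highest in the hfq mutant with OxyS, and chiP, oppA and trpE were high in both hfq libraries.

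The second comparison asked what differs with OxyS in cells without Hfq. In the hfq mutant 94 of 2743 compared genes were higher with OxyS and 63 were lower. Iron uptake genes controlled by the repressor Fur stood out: 35 of 36 compared members were higher and none was lower, with a median log2 ratio of 2.09, or 4.25-fold, at percentile 100. The enterobactin receptor gene fepA (b0584) went from 38.7 to 524.8 CPM (log2 ratio 3.76, 3.64 to 3.88). Other receptors for iron complexes were close behind, fiu at 3.61 (3.44 to 3.79), cirA at 3.58 (3.47 to 3.70) and fhuE at 3.20 (3.05 to 3.38). Enterobactin synthesis and release genes were also higher, entF at 3.53 (3.40 to 3.68), entE at 3.53 (3.28 to 3.83), fes at 3.53 (3.21 to 3.95), entB at 3.51, entC at 3.41, entH at 2.80 and entA at 2.73, as was the transporter gene fepC at 2.97.

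Heat shock genes were higher as a group in this pair. Of 21 compared members 14 were higher and none was lower, with a median of 1.22 at percentile 100. The small heat shock protein genes ibpB and ibpA were at 2.32 (2.24 to 2.40) and 2.06, the disaggregase gene clpB at 1.46, hslR at 1.40, and the chaperone gene dnaK at 1.39 (1.38 to 1.40). In the SOS regulon, the DNA damage response controlled by LexA, 5 of 21 genes were higher (8 with total counts) and none was lower, median 0.67 at percentile 100, with dinI at 1.81 (1.56 to 2.08), the division inhibitor gene sulA at 1.42, yebG at 1.28 and recN at 1.15. In the OxyR regulon 5 of 18 were higher, with a median of 0.07 at percentile 98.6 that turned to -0.07 at a mean CPM of at least 50. The higher members were genes that also answer to iron: fhuF at 2.09, a gene on the iron list too, and the iron-sulfur assembly genes sufD, sufS and sufC at 1.48, 1.42 and 1.36 were the largest. The superoxide response regulator gene soxS was at 2.27 (2.10 to 2.46), and it was the sole called gene of 16 in the SoxRS and Mar list, whose median was -0.13 at percentile 46.8 and 0.13 with total counts. Within the Qin prophage list 1 of 5 genes was called, gnsB at 1.31, with a median of 0.61 at percentile 99.8. Next to hfq, miaA was at 1.59 (1.57 to 1.62), and the list of hfq neighbours had a median of 0.65 at percentile 100.

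Lower genes in the hfq mutant with OxyS included the glucitol operon, the maltose genes and the isc operon for iron-sulfur cluster assembly, 3 lists put together after the values were seen. In the isc operon 8 of 8 genes were lower, median -1.82, with iscS at -2.12 (-2.14 to -2.09), iscU at -2.02, iscR at -1.92, iscA at -1.86 and hscB at -1.77. In the glucitol operon 4 of 5 were lower, median -2.37, with srlB at -2.82 (-3.19 to -2.53), srlD at -2.73, srlE at -2.37 and srlA at -2.25. Of 10 maltose genes 6 were lower, median -1.19, with the maltoporin gene lamB at -2.40 (-2.43 to -2.38), malM at -2.39 and malE at -1.75. All 3 medians stood at percentile 0, which is no support for a change, since the lists were put together after these values were seen. Against wild type with OxyS, the hfq mutant with OxyS had medians of -0.21 for the glucitol operon, -0.15 for the maltose genes and -0.89 for the isc operon. The hfq mutant with vector lay above wild type with vector by 2.82, 0.26 and 1.44. Among the lists fixed beforehand, the iron-using proteins that the small RNA RyhB represses had 5 of 15 lower, 4 of them isc genes, with a median of -0.59 at percentile 0.29. Flagella and chemotaxis genes had 5 of 50 lower and 50 of 50 below 0, with a median of -0.49 at percentile 0.08; fliD was at -1.20 and flgE at -1.09, and with total counts none of the 5 was called, fliD being at -0.94. Oligopeptide transport genes of the GcvB list, oppB at -1.20, oppC at -1.14, oppD at -1.08 and oppA at -1.07, were the 4 lower members of 24 in that list, whose median was -0.35 at percentile 3.41; with total counts 0 of them were called, oppB being at -0.93. The Spot 42 list had 2 of 14 lower (median -0.58, percentile 0.02), both from the glucitol operon, and the TCA cycle had 1 of 16, sucC, which went from 8536 to 4254 CPM and was not called with total counts (median -0.58, percentile 1.87). Anaerobic respiration genes had a median of -0.63 at percentile 0 and the lac operon one of -0.74 at percentile 2.12, with no gene called in either; lacZ, lacY, lacA and lacI were at -0.96, -0.81, -0.67 and -0.39.

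Porin and channel genes went both ways, with 4 of 19 higher, fepA, cirA, fiu and fhuA, all receptors for iron complexes, and 2 lower, lamB and ompW, of which 1 was called with total counts; the median of -0.27, at percentile 56.5, turned to 0.14 with ratios centred by abundance. Cell division genes had 1 of 23 higher, sulA (median 0.13, percentile 100).

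None of the 9 earlier OxyS targets was called in the hfq mutant, and their median was 0.02 at percentile 86.1. The value of rpoS was 0.29 (0.26 to 0.33), and those of cspC, yobF, flhD and flhC were 0.24, -0.05, -0.23 and -0.22. Of fhlA, ybaY, wrbA and nusG the values were 0.08, 0.09, -0.05 and 0.02.

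The count of lower genes in this pair depended on scaling. The TMM factors of these 2 libraries lie far apart. With total counts the median of all genes moved by 0.26, so that 121 genes were higher and 23 lower. This raised the higher share from 59.9% to 84.0%. That share was 87.7% with total counts without the 20 most abundant genes and 89.2% with the authors' RPKM. The listed total of the hfq mutant with vector lacks the 1001592 further reads that its RPKM values imply. Total counts and RPKM therefore scale that library differently. The ratio fell with abundance across genes, with a Spearman rho of -0.30, and the higher share was 70.3% and 71.5% with ratios centred by coding length and by abundance. Of the 157 called genes, 104 had the hfq mutant with OxyS as the library farthest from the median of the 4, and 48 the hfq mutant with vector.

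The changes with OxyS in wild type and in the hfq mutant had little in common. Across 2741 genes compared in all libraries, their log2 ratios had a Pearson r of 0.06 and a Spearman rho of 0.04; these ratios share no library, and genes are not independent replicates. Of 37 genes higher in wild type and 91 higher in the mutant, 2 were higher in both, entC and the sulfate-binding protein gene sbp, where independent lists would share 1.23. Another 4, cysH, cysI, cysJ and cysM, were higher in wild type and lower in the mutant, where independent lists would share 0.85. The calls are near the size needed: with total counts cysJ and cysM were not called in the mutant, and with RLE factors sbp was not. Of these genes sbp and cysM were named after their values were seen. No gene was lower in both.

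**Figure D2:**
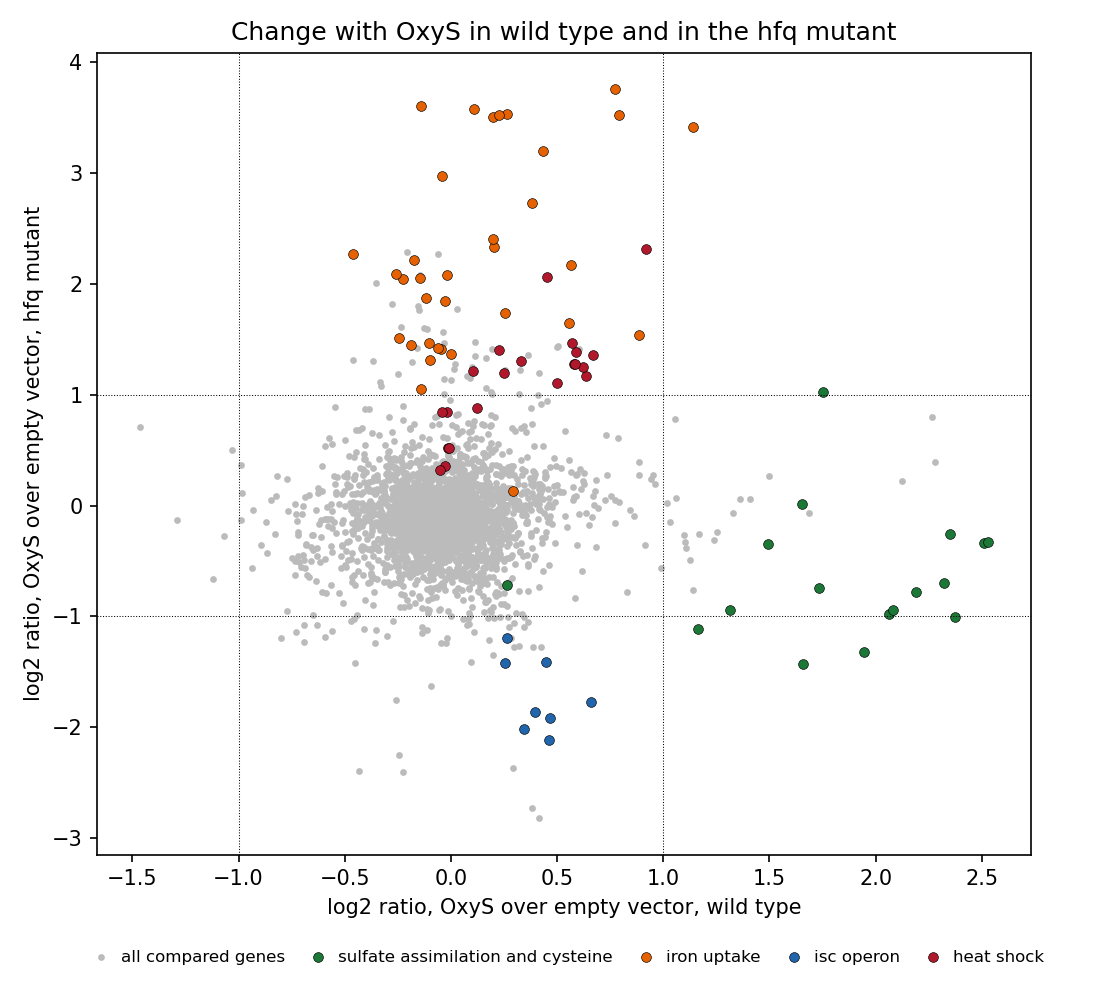
Log2 ratio of OxyS over empty vector in wild type (x axis) and in the hfq mutant (y axis) for 2741 genes, 1 library per group, with dotted lines at the size needed for a call. The sulfate and cysteine genes lie to the right, with a median of 1.94 on the x axis, the iron uptake and heat shock genes lie at the top, with medians of 2.09 and 1.22 on the y axis, and the isc operon lies at the bottom.

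The difference of both OxyS ratios, wild type minus hfq mutant, was used to describe the dependence of the change on Hfq. With 1 library per group, a difference in culture of any library enters it and cannot be told apart from such a dependence. The difference passed the rule of size for 193 of 2741 genes, 105 with a higher ratio in wild type and 88 with a lower one. The largest differences in favour of wild type were those of cysJ at 3.38 (3.30 to 3.46), cysI at 3.26 (3.19 to 3.33), srlB at 3.24 (2.74 to 3.73), srlD at 3.11, cysH at 3.08 and cysN at 3.05. The largest in the other direction were iron uptake genes, fiu at -3.75 (-3.98 to -3.51), cirA at -3.47 (-3.63 to -3.32), entB at -3.31, fes at -3.31, entF at -3.27 and fepC at -3.02. By list, 32 of 34 iron uptake genes were called with the lower ratio in wild type and 33 lay below 0, with a median of -2.17 at percentile 0. Of 17 sulfate and cysteine genes, 15 were called with the higher ratio and all 17 lay above 0, with a median of 2.85. The sulfate and cysteine list was put together after the values were seen. Of the 9 earlier OxyS targets 1 was called (2 with the authors' RPKM), cspC, with a difference of -1.01 (-1.08 to -0.94), and it was not called with ratios centred by coding length. All 21 heat shock genes had differences below 0, 4 of them called (11 with total counts), with a median of -0.76 at percentile 0. In the SOS list 5 of 21 were called lower (8 with total counts), median -0.58, and in the flagella list 9 of 50 were called higher (4 with total counts), median 0.39 at percentile 98.8. The share with the higher ratio in wild type, 54.4%, was 30.3% with total counts, 27.3% with total counts without the 20 most abundant genes and 24.2% with the authors' RPKM.

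The third comparison asked what differs between hfq mutant and wild type with the empty vector. It was the largest: 270 of 2722 compared genes were higher in the mutant and 93 were lower. The chitoporin gene chiP (b0681, positions 708334 to 709740) went from 15.7 to 5313 CPM, a log2 ratio of 8.39 (8.24 to 8.57) or 336-fold, and chiQ, next to it, was at 7.43 (7.10 to 7.92). The tryptophan transporter gene mtr was at 4.58 (4.44 to 4.75), and the tryptophan synthesis genes trpE, trpD and trpC were at 4.37, 3.30 and 1.57. In the list of histidine, tryptophan and branched-chain biosynthesis 9 of 26 were higher and 1 was lower, with a median of -0.03 at percentile 48.0.

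Genes of the GcvB-repressed list, mostly of amino acid and peptide transport, were higher together, 20 of 24 with none lower. Their median was 2.08, or 4.21-fold, at percentile 100. The periplasmic binding protein genes oppA and dppA were at 3.81 (3.79 to 3.83) and 3.44 (3.41 to 3.47), and dppB and dppF at 3.26 and 3.03. The TCA cycle had 13 of 16 higher and none lower (median 1.39, percentile 100), with the succinyl-CoA synthetase genes sucC and sucD at 1.93 and 1.88 and the citrate synthase gene gltA at 1.49. RyhB-repressed iron-using proteins had 10 of 16 higher and none lower (median 1.19, percentile 100), with iscR at 1.69 and iscS at 1.59, but in the OxyS pair the list median was 0.25 and iscR and iscS lay at -0.69 and -0.99. Carbon use genes repressed by Spot 42 had 6 of 15 higher and none lower (median 0.94, percentile 100), with srlE at 3.36, srlA at 2.97 and paaK at 2.02. The TCA cycle, RyhB and Spot 42 lists share genes, with sdhC in each of them, so they are not separate results. In lists put together after the values were seen, all 5 arginine succinyltransferase genes were higher (median 3.28; astC at 3.52 and astA at 3.37), as were all 6 genes of lactate and acetate uptake (median 3.31; lldP at 3.48, acs at 3.43 and actP at 3.40) and all 17 sulfate and cysteine genes (median 2.79), although the last list had a median of -0.15 between hfq mutant and wild type in the OxyS pair.

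Stress and envelope genes were higher in part. The envelope stress list of the sigma factor RpoE had 6 of 20 higher and none lower (median 0.37, percentile 98.6), with yfeK at 2.23, rseA at 1.85, degP at 1.76 and rpoE itself at 1.57. The heat shock list had 4 of 21 higher (median 0.45, percentile 99.6), with ibpB at 3.52 and ibpA at 2.11. Porin and channel genes had 5 of 19 higher and 1 lower (median 0.20, percentile 88.4), among them lamB at 2.40 and ompX at 1.81. Flagella and chemotaxis genes had 2 of 50 higher, fliZ at 1.48 and fliA at 1.14, and 48 of 50 were above 0 (median 0.50, percentile 100). The RpoS general stress list went both ways, with 2 of 22 higher, csiD at 1.67 and gabD at 1.57, and 2 lower, cfa at -1.94 and osmY at -1.31. Its median of 0.31, at percentile 98.5, turned to -0.27 at a mean CPM of at least 50. In the lac operon lacY alone was called, from 2169 to 6135 CPM, and lacZ, lacA and lacI were at 0.48, 0.84 and 0.66. In the OxyS pair lacY, at 0.67, was not called, and lacZ, lacA and lacI were at -0.67, 0.26 and 0.43.

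Lower genes in the hfq mutant were led, after hfq itself, by asnA at -5.14 (-5.32 to -4.98) and the glycolate oxidase genes glcD at -4.55 (-4.75 to -4.38), glcE at -4.00 and glcF at -2.63. All 6 genes of the glycolate operon were lower, a list put together after the values were seen. The type 1 fimbria genes fimA, fimI and fimD were at -3.12, -2.40 and -2.04, and they were the 3 lower genes of 8 in the list of curli, cellulose and fimbriae (median -0.56, percentile 0.16). Other lower genes were the magnesium transporter gene mgtA at -3.02, the phosphodiesterase gene yahA at -2.93, the glycine betaine transporter gene proV at -2.62, ykgE at -2.51 and the aspartokinase gene lysC at -2.30. Ribosomal protein genes lay below 0 in 54 of 54 cases, with a median of -0.79 at percentile 0, and 3 were called, rpmE at -1.11, rpsT at -1.04 and rplM at -1.03, against 16 with the authors' RPKM and 0 with ratios centred by abundance. Genes of transcription elongation and termination had 12 of 13 below 0 and none called (median -0.52, percentile 1.24). Iron uptake genes had 4 of 27 lower, entE at -1.23, fiu at -1.22, fecD at -1.13 and entC, from 18.1 to 8.94 CPM, with a median of -0.67 at percentile 0.

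The same genotype comparison could be made in the OxyS pair, which shares no library with the vector pair. There 280 of 2746 genes were higher in the mutant and 206 lower. Over 2690 genes compared in both pairs, 162 were higher in both, of 259 and 266, where independent lists would share 25.6; 67 were lower in both, of 93 and 203, where independent lists would share 7.0. Only 4 genes were called in opposite directions, entC, entE, fiu and hscB. The Pearson r of the log2 ratios across genes was 0.78 and the Spearman rho 0.73. The ratios of chiP, mtr, oppA, dppA, glcD and asnA in the OxyS pair were 8.30, 5.09, 2.65, 4.16, -3.90 and -2.96. Other genes and groups differed between the pairs. With vector and with OxyS, lamB was at 2.40 and 0.23 and srlE at 3.36 and 0.70. List medians in the same order were 2.79 and -0.15 for sulfate and cysteine genes, 1.44 and -0.89 for the isc operon, 2.82 and -0.21 for the glucitol operon, 1.19 and 0.25 for RyhB-repressed genes, 1.39 and 0.66 for the TCA cycle, 0.50 and 0.06 for flagella, and -0.67 and 1.55 for iron uptake.

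In an additive edgeR quasi-likelihood model over the 4 libraries, 381 of 2741 genes differed by genotype at a Benjamini-Hochberg adjusted p of 0.05, 215 higher and 166 lower in the mutant. The same edgeR model called 0 genes for the plasmid, averaged over both backgrounds, with a smallest adjusted p of 0.87 and 123 genes at an unadjusted p under 0.05. A change with OxyS in a single background breaks the model's assumption that effects add, so this result does not exclude such changes. The higher share of the genes called by size, 74.4%, was 62.4% with total counts without the 20 most abundant genes and 58.7% with the authors' RPKM.

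**Figure D3:**
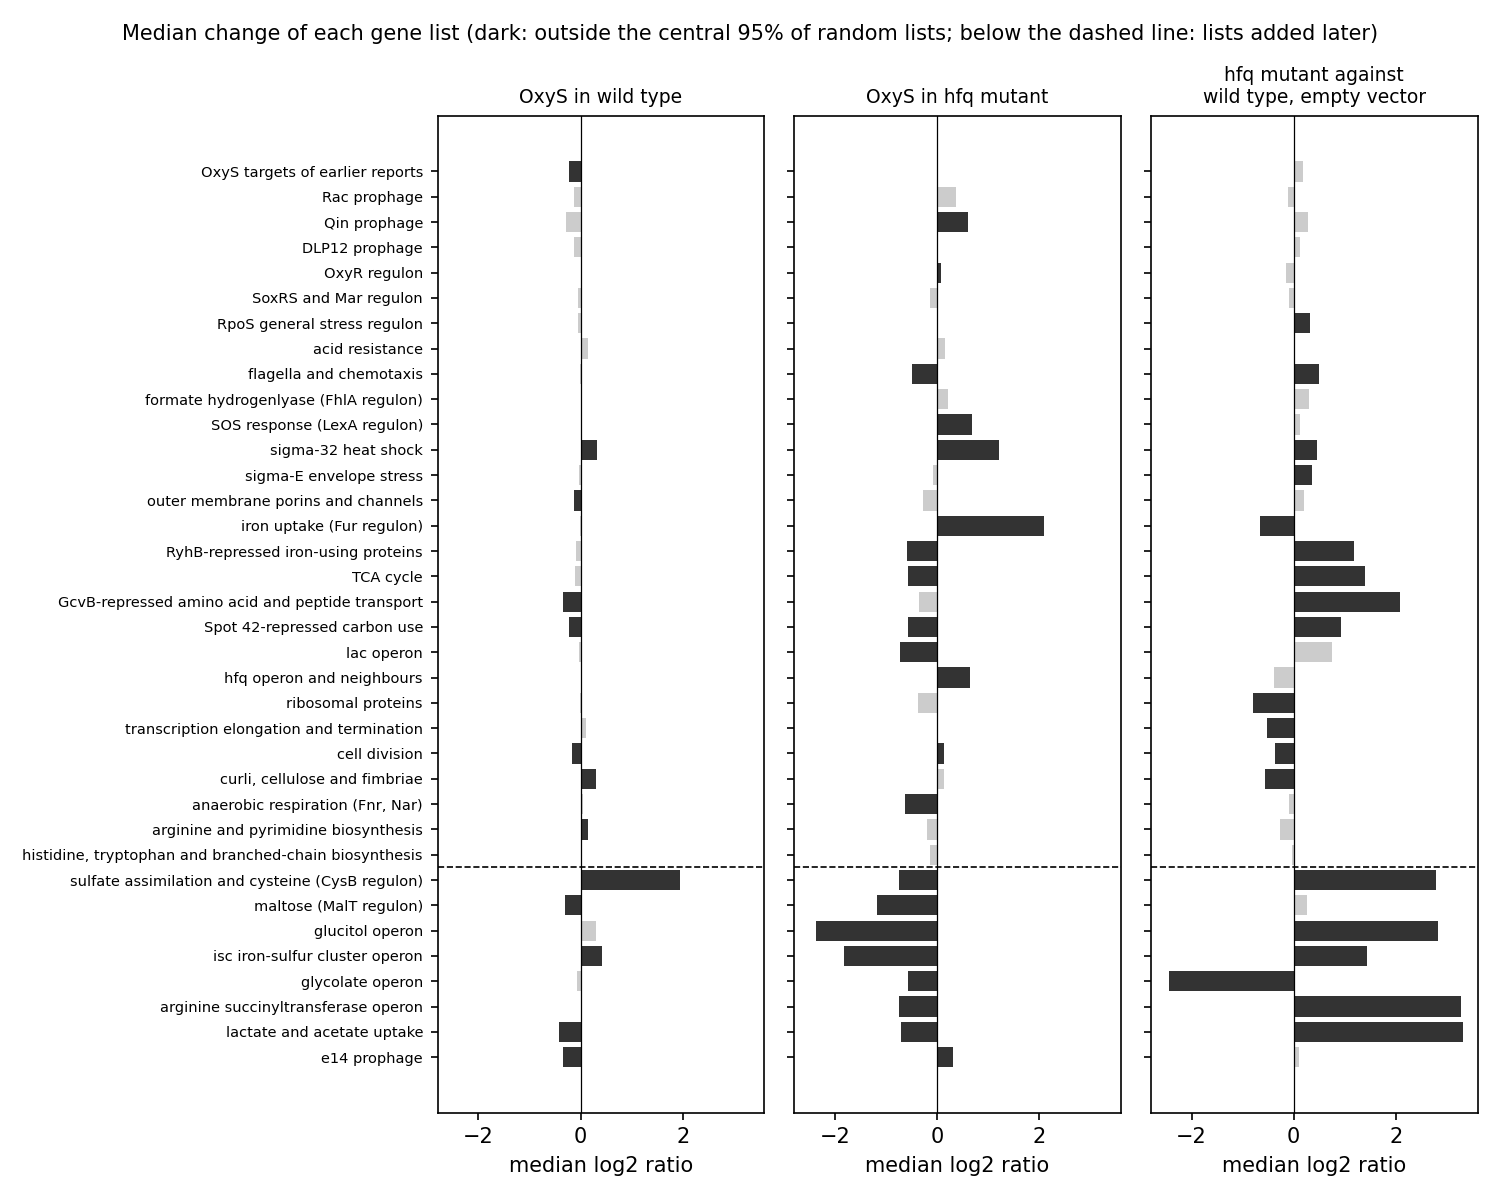
Median log2 ratio of the compared members of each gene list in the 3 comparisons, with dark bars for medians outside the central 95% of random lists matched on size and abundance, and lists put together after the values were seen below the dashed line. Iron uptake reached 2.09 with OxyS in the hfq mutant, and the GcvB-repressed list reached 2.08 in the hfq mutant against wild type.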

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

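The tests in this part were chosen after the result was seen, except the medians after centring by abundance and by coding length, whose bounds were set before those medians but after the trends themselves had been seen. Wild type and hfq mutant differed in direction for 4 genes called with OxyS in both. The difference of the OxyS log2 ratios, wild type minus mutant, was 3.08 for cysH, 3.26 for cysI, 3.38 for cysJ and 2.28 for cysM. With 1 library per group the difference itself was not tested, and with total counts cysJ and cysM were not called in the mutant.

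The sulfate and cysteine genes were higher with OxyS in wild type by a median log2 ratio of 1.94. A trend with coding length does not account for it, since the median was 1.93 once ratios were centred in 10 groups of genes by length. General occupation of Hfq by OxyS would raise genes that are higher without Hfq. Of 11 other such lists, 3 lay below random lists with OxyS in wild type (GcvB-repressed -0.34, Spot 42-repressed -0.23, lactate and acetate uptake -0.42). Another 2 lay above (isc operon 0.42, heat shock 0.33) and 6 within. The lactate and acetate, isc and glucitol lists were put together after the values were seen, so their places are no support. Some of the 11 lists share genes. They were picked by a ratio to wild type with vector, the library that the OxyS ratio also uses. General occupation of Hfq by OxyS therefore stays open. A low level in the single library of wild type with vector may account for the pattern, since the other 3 libraries lay above it by a median of at least 1.87. An effect of OxyS on these genes stays open beside it, because both would look alike in 1 library per group.

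The iron uptake genes were higher with OxyS in the hfq mutant by a median log2 ratio of 2.09. A low level in the hfq mutant with vector is not the whole of it: against wild type with OxyS the same genes in the hfq mutant with OxyS had a median of 1.55, although the mutant with vector lay at -0.67 against wild type with vector. A trend with abundance left a median of 2.16 after centring in 10 groups of genes by abundance. A difference in culture or handling of the hfq mutant with OxyS, of which there was 1 library, could also produce the pattern and cannot be told apart from an effect of OxyS without Hfq.

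The authors' RPKM values of the hfq mutant with vector imply 1001592 reads beyond its listed counts, a signal outside the counts that were compared. The gene fliC was listed at 0 there, in the counts and in the RPKM. A value lost in making the table is a candidate explanation, since the gap was at most 1921 reads in the other libraries, and fliC held 3.31% to 4.61% of their counts against the missing 5.56%. A loss of flagellin together with the other flagellar genes would lower them, and the other 50 genes of that list had a median of 0.50 against wild type. That median does not bear on a loss of fliC alone.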

How the results depend on the processing

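The alternatives fixed beforehand were those listed in the methods. TMM without fliC, the fliC cell taken as 0, the OxyS pair, the additive model and the centred ratios were chosen after seeing the data. No paired analysis was possible because each group has 1 library and the labels number no replicates; the additive model does compare the plasmids within each background. No library could be left out, also for want of replicates. Under the settings that recomputed these same ratios no called named gene changed sign. In the OxyS pair some genes called with vector did. There entC, entE and fiu, called lower in the mutant with vector, were called higher at 1.27, 1.51 and 2.53. The genes iscR and iscS, called higher with vector, lay at -0.69 and -0.99. The ratio of hfq between wild type and mutant stayed within its counting interval with each scaling and with the authors' RPKM. The correlation of both OxyS ratios, 0.06, was 0.00 (0.001) at a mean CPM of at least 50. Where a count below moved, the cause was not tested beyond the setting's own construction.

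Scaling moved mainly the pair of hfq libraries. RLE factors gave 8 lower genes with OxyS in wild type. Total counts gave 23 lower genes with OxyS in the hfq mutant, and 66 higher and 152 lower for Hfq dependence. Total counts without the 20 most abundant genes gave 19, 63 and 168. The authors' RPKM gave 17, 57 and 179, and 156 lower genes in the hfq mutant against wild type. Centring by coding length and by abundance each gave 41 lower genes with OxyS in the hfq mutant.

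With no filter on low counts there were 116 higher and 13 lower genes with OxyS in wild type, 148 higher with OxyS in the mutant, 147 lower in the mutant against wild type, and 314 for Hfq dependence, 170 higher and 144 lower. With a mean CPM of at least 50 these were 17, 3, 57, 49 and 116, with 44 lower for Hfq dependence. At a log2 ratio of at least 2 there were 11 higher and 0 lower with OxyS in wild type, 27 and 8 in the mutant, 88 and 17 in the mutant against wild type, and 48 for Hfq dependence, 23 higher and 25 lower. The OxyS pair gave 206 lower genes in the mutant and the additive model 166; that model gave 0 genes, higher or lower, for the plasmid.

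Medians of some lists changed sign. Transcription elongation and termination with OxyS in the hfq mutant went from 0.02 to -0.003 with RLE factors. At a mean CPM of at least 50 the OxyR list in that pair went from 0.07 to -0.073, the RpoS list in the mutant against wild type from 0.31 to -0.268, and the list of histidine, tryptophan and branched-chain biosynthesis for Hfq dependence from 0.33 to -0.082; the last was -0.026 with the authors' RPKM. Medians within that range changed sign more often. The ribosomal protein list with OxyS in the hfq mutant, at -0.38, was at 0.01 with ratios centred by abundance. Earlier OxyS targets in that pair went from 0.02 to -0.003 with RLE factors. The Rac list with OxyS in wild type went from -0.13 to 0.17 with no filter on low counts.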

Other observations

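The prophage lists Rac and DLP12 and the formate hydrogenlyase list stayed within the central 95% of random lists. The Rac and DLP12 prophage lists had no called gene in any of the 3 comparisons, with medians of -0.13 and -0.13 with OxyS in wild type, 0.36 and 0.02 with OxyS in the hfq mutant, and -0.10 and 0.12 in the hfq mutant against wild type. These rest on few genes: 3 or 4 of 28 Rac members and 4 of 23 DLP12 members passed the CPM filter. With no filter on low counts the Rac medians turned to 0.17 with OxyS in wild type and 0.06 in the hfq mutant against wild type. The formate hydrogenlyase list, controlled by FhlA, had no called gene among 6 and medians of 0.00, 0.21 and 0.30. Acid resistance genes were mostly under 10 CPM, and of the 3 compared in each OxyS pair none was called. The lists of Hfq-binding small RNAs and of Hfq-independent stable RNAs had 0 rows and were not analysed here. The e14 prophage list, put together after the values were seen, had 4 of 9 genes higher with OxyS in the hfq mutant, with a median of 0.32 at percentile 99.8, and with OxyS in wild type 5 of 5 below 0 and none called, with a median of -0.35 at percentile 0.82.

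Of the tests in this part, the reading of covariances and the wording of the abundance trend were chosen after the result was seen. The bounds on both correlations were set before those were computed, though the additive model, which bears on the second, had been seen. If OxyS occupied Hfq in general, the OxyS ratios in wild type could resemble the hfq ratios across genes. The Pearson r was 0.15 with the vector pair, which shares wild type with vector, and -0.19 with the OxyS pair, which shares wild type with OxyS. Unchanged libraries simulated with counting error alone gave 0.45 and -0.53. The covariances were 0.0421 and -0.0554 against simulated values of 0.0025 and -0.0032. They depart from the simulation in opposite directions, as differences peculiar to the shared library would, so the test does not decide. The bound set beforehand, an r at or below 0 as evidence against, was wrong because the shared library alone gave a simulated -0.53.

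If loss of Hfq acts alike with and without OxyS for most genes, the hfq ratios of both pairs would correlate, and their Pearson r was 0.78 across 2690 genes. Medians of some groups differed between the pairs, each from single libraries: with vector and with OxyS they were -0.67 and 1.55 for iron uptake, 2.79 and -0.15 for sulfate and cysteine genes, and 1.44 and -0.89 for the isc operon. Whether this lies in Hfq, OxyS or the culture of 1 library was not tested. If the OxyS ratio in the hfq mutant falls with abundance, abundant genes would lie lower, and the Spearman rho was -0.30, with medians of -0.41 in the most abundant of 10 groups of genes and 0.05 in the least abundant. What lies behind the trend was not tested.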
